A study of Nothobranchius furzeri with 10 samples.

How the data were processed

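Gene expression was measured by RNA sequencing in 10 brain samples of male Nothobranchius furzeri, 5 in each of 2 groups. Per the labels' protocols, libraries were made with the Illumina TruSeq RNA kit, version 2. Per the submitters' processing notes, bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4 were used; the genome build, the annotation and the counting options, strand included, are not given in the sources used here. The deposited count table holds whole-number read counts per gene for each library, not normalised. The deposited RPKM table holds reads scaled to gene length and library size for the same genes and libraries. Columns were assigned to samples by title, and groups were taken from the perturbation label.

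The count table lists 26739 genes, of which 3924 had no count in any library. Library totals ran from 18489730 to 24486735 counts. The median tested gene had 18.8 CPM. Replicates differed by more than counting error, so the spread between them sets the precision. The median SE of a log2 fold change was 0.11 and the common biological coefficient of variation 0.177. Reads shared between near-identical or overlapping genes could not be told apart from the counts.

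Differences between the groups were tested in R 4.3.3 with edgeR 4.0.16 on the deposited counts. Genes were filtered with the default settings of filterByExpr (a minimum count of 10 and a minimum total of 15), which left 18976 genes holding 99.94% of the counts. Library sizes were scaled by TMM, with factors of 0.990 to 1.01. A quasi-likelihood model with robust dispersion estimates and the group as the only term was fitted to all 10 libraries, and p-values were adjusted by Benjamini-Hochberg with a limit of 0.05. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM (counts scaled to library size) use TMM-scaled library sizes, except in the fits on own library totals. The principal component analysis used log2 CPM with a prior count of 2. Library measures and components were compared by two-sided exact permutation tests over the 252 assignments of 5 of 10 libraries, whose smallest possible p is 0.0079.

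The test, the samples, the gene lists and the alternatives, except the fits on values recomputed with own library totals, were chosen before the data were examined. The rule for naming genes asked for gene names, which the tables do not pair with the identifiers. It was replaced by the 2 identifiers with the lowest p in each direction, whether or not they passed. A RefSeq gene table of 38438 genes for the assembly NfurGRZ-RIMD1 matched 0 of the identifiers. The planned tests of gene lists, of cell type markers, of miR-29 targets and of genes with miR-29 sites in their 3′ untranslated regions could therefore not be run, and contamination by other tissues was not checked.

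The deposited RPKM values were checked against the counts. For the 4159 genes with at least 1000 counts in each library and RPKM above 5, the gene length implied by count, RPKM and library total should be equal in all libraries. Its median coefficient of variation was 11.48% with each library's own total and 0.001% with the 10 totals assigned in turn down the rows. Lengths for all genes with nonzero RPKM were taken with the totals in turn, and RPKM with own totals were computed from them and the counts. Both forms were tested with limma 3.58.1 (limma-trend) on log2(RPKM + 0.1) and log2(RPKM + 1) for the genes passing the count filter. These lengths also served to remove trends with length, for 17586 tested genes with RPKM reaching 1 and all nonzero entries given within rounding. Each library's smooth trend of log2 CPM on length and mean expression was fitted by local regression and entered as an offset. The edgeR test was then repeated. This replaced a comparison with gene sets matched on length and expression, which was dropped because choosing the genes by p had fixed its outcome. The log2 fold changes on these scales understate the change of low genes.

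Alternatives were the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, edgeR without robust estimation, RLE and upper quartile scaling, no count filter beyond removing genes with no counts, a filter of at least 50 counts in at least 5 libraries, an adjusted p limit of 0.1, leaving out each library, the number in the sample titles as a block, and 1 surrogate variable from sva 3.50.0. Replicates were compared by a chi-square over genes with at least 20 counts. Genes with high spread were the 500 with the highest SD of log2 CPM within groups against a trend on expression, and they were clustered by correlation with average linkage at a distance of 0.3. Figures were drawn with matplotlib 3.10.9.

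The scripts were tested on simulated data for the comparison of antagomiR-29a with scrambled control, with 18976 genes drawn at the means, dispersions and library sizes of the real libraries and 50 genes changed at each fold. The edgeR test recovered 14% of genes changed 1.25-fold, 54% at 1.5-fold, 86% at 2-fold and 88% at 3-fold. It called 123 genes, of which 2 were false, and 0 genes when none was changed. DESeq2 called 165 genes in the same simulated data, of which 24 were false. Genes were drawn independently, and those of the lowest expression were left unchanged. The real data gave 9 calls, so the Benjamini-Hochberg limit was laxer in the simulation and these shares may overstate recovery. The 0 calls do not carry over to real libraries, whose genes vary together: another split of them called 25 genes.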

Results

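RNA was profiled in whole-tissue brain samples of the turquoise killifish Nothobranchius furzeri, a short-lived annual fish used in research on vertebrate ageing. All 10 samples came from males of the strain MZM-0410p aged 22 weeks. Per the labels, 5 samples belonged to a group given a scrambled control and 5 to a group given antagomiR-29a at 100 pmol. The labels give no dose for the scrambled control. An antagomir is a chemically modified oligonucleotide complementary to a microRNA, which it binds and blocks. A scrambled control is an oligonucleotide of shuffled sequence with no intended target. The microRNA miR-29a belongs to the miR-29 family, whose known targets in mammals include collagens and other extracellular matrix genes. The route of delivery and the time between treatment and sampling are not given in the sources used here, and miR-29a itself was not analysed here.

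The libraries held between 18489730 and 24486735 counts assigned to genes. The mean total was 20870000 ± 2289000 in the scrambled control group and 21101000 ± 1761000 in the antagomiR-29a group (SD, n = 5 each). This difference was within the spread between replicates (two-sided exact permutation test, p = 0.873, Benjamini-Hochberg adjusted p = 0.929 over the 3 library measures). At least 1 count was found for 21558 ± 115 genes per control library and 21549 ± 104 genes per antagomiR-29a library (SD, n = 5 each; exact permutation p = 0.929, adjusted p = 0.929). The 10 most abundant genes took 3.76% ± 0.325 of the counts in the control group and 3.59% ± 0.237 in the antagomiR-29a group (SD, n = 5 each; exact permutation p = 0.381, adjusted p = 0.929). The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, part of which may be technical. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 11.9 to 28.9 over the 20 pairs within groups, and none was treated as a duplicate.

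The design asks which transcripts of the killifish brain differ between fish given antagomiR-29a and fish given a scrambled oligonucleotide. Of 18976 genes tested, 9 differed, of which 8 were higher and 1 was lower in the antagomiR-29a group (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p from 0.0156 to 0.0462). The 8 genes that rose did so by 1.36-fold to 1.88-fold, with a median log2 fold change of 0.78. The lowest adjusted p belonged to Nfu_g_1_010009, an abundant transcript at the expression percentile 98.8 of the tested genes, which averaged 343 ± 51.3 CPM (counts scaled to library size) in the control group and 646 ± 24.7 CPM in the antagomiR-29a group (SD, n = 5 each). The gene that fell, Nfu_g_1_010469, averaged 12.7 ± 0.94 CPM in the control group and 6.81 ± 1.2 CPM in the antagomiR-29a group (SD, n = 5 each). The deposited tables do not pair these identifiers with gene names, so the products of the 9 genes are not named here.

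The log2 fold change of Nfu_g_1_010009 was 0.91 with an SE of 0.09, a 1.88-fold rise (95% interval 0.71 to 1.12 on the log2 scale, edgeR adjusted p = 0.016). Its control libraries lay between 264 and 394 CPM and its antagomiR-29a libraries between 610 and 673 CPM, from 5702 to 15339 counts per library. A smaller and tighter rise was measured for Nfu_g_1_008034, from 64.0 ± 3.32 CPM to 86.9 ± 3.92 CPM (SD, n = 5 each). Its log2 fold change was 0.44 with an SE of 0.05, a 1.36-fold rise (95% interval 0.33 to 0.55, edgeR adjusted p = 0.020), from 1241 to 2116 counts per library. For Nfu_g_1_010469 the log2 fold change was -0.90 with an SE of 0.12 (95% interval -1.17 to -0.63, edgeR adjusted p = 0.035). Its control libraries lay between 11.7 and 13.7 CPM and its antagomiR-29a libraries between 5.07 and 8.08 CPM, on 103 to 333 counts per library, so it rests on fewer counts than the other genes named. The next gene by p among those with lower values, Nfu_g_1_018930, did not pass (log2 fold change -0.49, SE 0.08, edgeR adjusted p = 0.082), with 35.4 ± 2.52 CPM in the control group and 25.3 ± 2.61 CPM in the antagomiR-29a group (SD, n = 5 each).

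**Figure D1:**
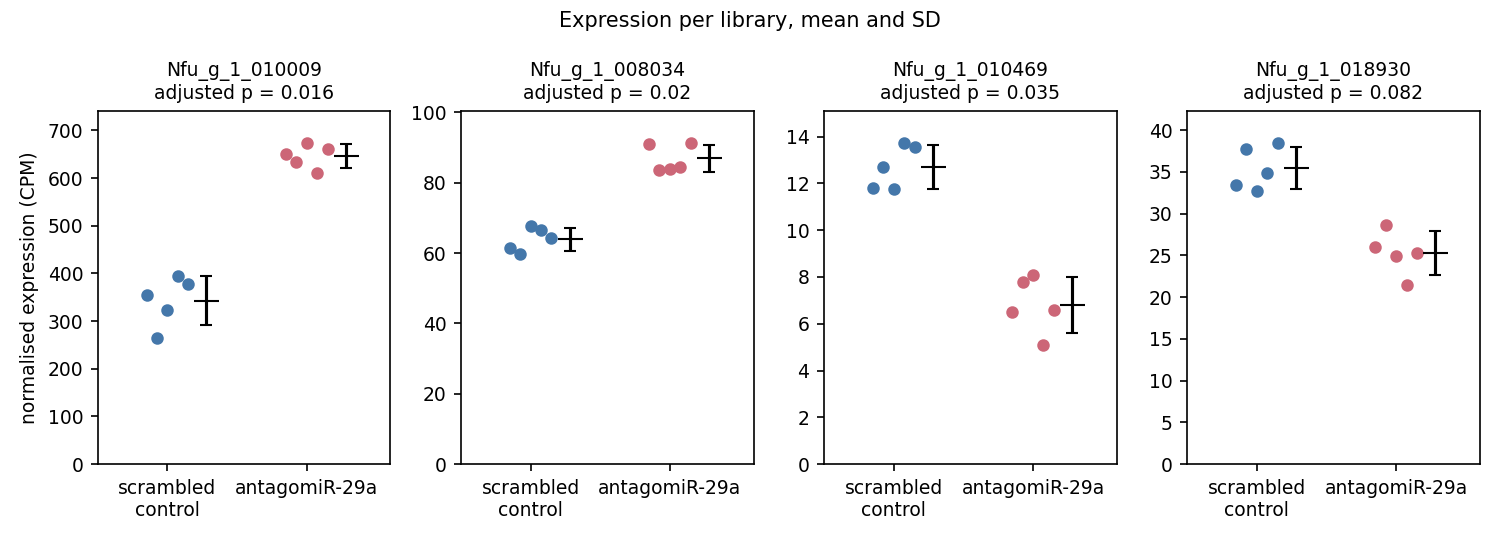
Normalised expression in CPM (y axes, from 0) of 4 genes in the scrambled control (blue) and antagomiR-29a (red) libraries; each point is 1 library, and the black bar and whiskers give the mean and SD over 5 libraries. The ranges of the groups do not overlap in any of the 4 panels, and Nfu_g_1_018930, at an adjusted p of 0.082, did not pass the test.

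In each of the 9 called genes the ranges of the groups did not overlap, with all 5 antagomiR-29a libraries on the same side of all 5 control libraries. This is likely for genes picked by a low p in the same libraries. Over all tested genes, 214 genes had such non-overlapping groups, or 1.13%, against the 0.79% (151 genes) that chance gives with 5 against 5. These divided into 113 genes higher and 101 genes lower in the antagomiR-29a group, and their number was not set against other splits of the libraries. The called genes covered a wide range of abundance, with control means from 8.75 to 343 CPM, where the median tested gene had 18.8 CPM.

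With the limit relaxed, genes leaned towards higher values in the antagomiR-29a group, the 9 called genes included. At an unadjusted p under 0.001 there were 54 genes, 43 higher and 11 lower, where 19 are due to independent chance. At an unadjusted p under 0.05 there were 1122 genes, 630 higher and 492 lower, where 949 are due to independent chance. Neither number stood apart from regroupings of the same libraries. Of 100 splits into 5 and 5, the real one included, 6 gave at least 54 genes and 23 gave at least 1122. The lean at an unadjusted p under 0.05 was not set against these splits. With the adjusted p limit at 0.1 in place of 0.05, edgeR called 18 genes, 16 higher and 2 lower. The largest change among the 9 genes added by this limit had a log2 fold change of 1.52 with an SE of 0.25 (edgeR adjusted p = 0.082).

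**Figure D2:**
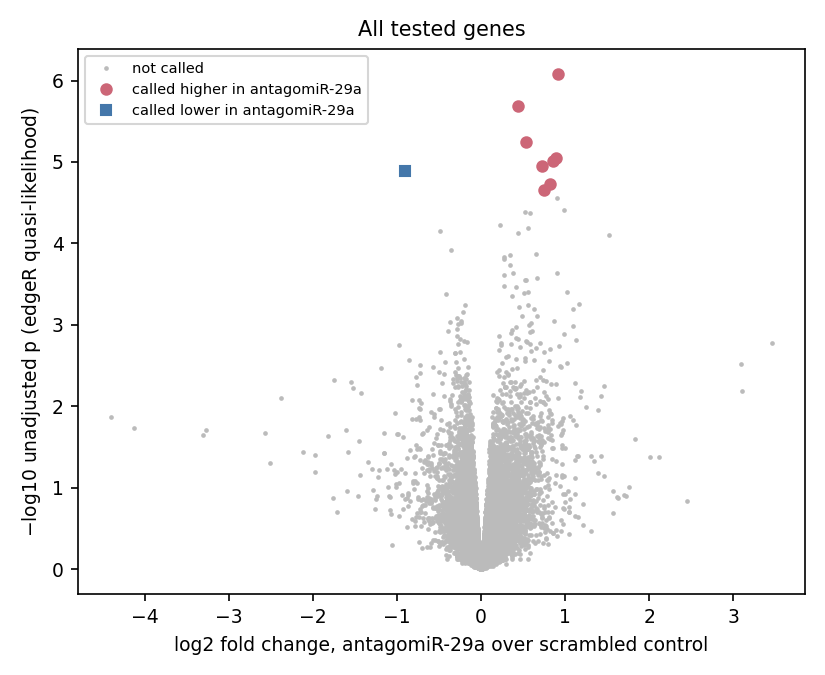
Each point is 1 of the 18976 tested genes, with the log2 fold change of antagomiR-29a over scrambled control on the x axis and -log10 of the unadjusted edgeR p on the y axis. The 8 genes called higher are red circles and the gene called lower is a blue square; all 9 lie within 1 log2 unit of no change.

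The median log2 fold change of all tested genes was 0.003, with an interquartile range of -0.068 to 0.087. The 95% interval of the log2 fold change lay within 1 unit of no change for 17290 genes, or 91.1%, and within a 1.5-fold change for 75.9%. Fitted log2 fold changes beyond 1 unit were found for 102 genes, 53 higher and 49 lower. None of these 102 passed the edgeR test, 53 of them had an unadjusted p under 0.05, and DESeq2 called 8 of them. In a principal component analysis of the 1000 most variable genes, the groups were not separated along the first component (26.9% of the variance, exact permutation p = 0.627), the second (20.7%, p = 0.452) or the third (11.8%, p = 0.421), with an adjusted p of 0.627 for each.

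The number of called genes changed with the test and when single libraries were left out. A fit without 1 library has fewer samples, so lost power and the influence of that library were not told apart. DESeq2 called 73 genes, 57 higher and 16 lower, all 9 edgeR calls among them. With edgeR, leaving out control replicate 1, control replicate 3, antagomiR-29a replicate 1 or antagomiR-29a replicate 5 gave 0 calls, with 1058, 1253, 1209 and 933 genes at an unadjusted p under 0.05. Leaving out control replicate 2 gave 1 call, control replicate 5 or antagomiR-29a replicate 3 gave 3 calls, and antagomiR-29a replicate 4 gave 4 calls, all of them among the 9. Leaving out control replicate 4 gave 3 calls, of which 2 were among the 9, and leaving out antagomiR-29a replicate 2 gave 8, of which 6 were. The log2 fold changes themselves moved little in these fits, between 0.83 and 0.97 for Nfu_g_1_010009, between 0.42 and 0.46 for Nfu_g_1_008034 and between -0.97 and -0.81 for Nfu_g_1_010469. Their highest adjusted p without 1 library was 0.0822 for each of Nfu_g_1_010009 and Nfu_g_1_008034, both without control replicate 1, and 0.143 for Nfu_g_1_010469, without antagomiR-29a replicate 5. The call of Nfu_g_1_010469 was kept only without antagomiR-29a replicate 4, at an adjusted p of 0.0461.

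The comparisons above used the deposited counts, as chosen beforehand, and the deposited RPKM values served only for alternative fits. These RPKM values did not scale with each library's own total. All but 4 of the 215535 nonzero RPKM entries were given, within the rounding of 0.0005, by the count, 1 length per gene and the 10 library totals taken in turn down the table, so that neighbouring entries of a library were divided by totals of different libraries. With each library's own total, 9.21% of the entries were given. The divisor deviated from the library's own total by between -24.49% and 32.43%, and 10.0% of the entries were divided by the right one. For the limma-trend test this raised the median SE of the log2 fold change from 0.104 with own totals to 0.165, and the number of called genes was 0 with the deposited values and 7 with own totals, where 436 and 1059 genes had an unadjusted p under 0.05.

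**Figure D3:**
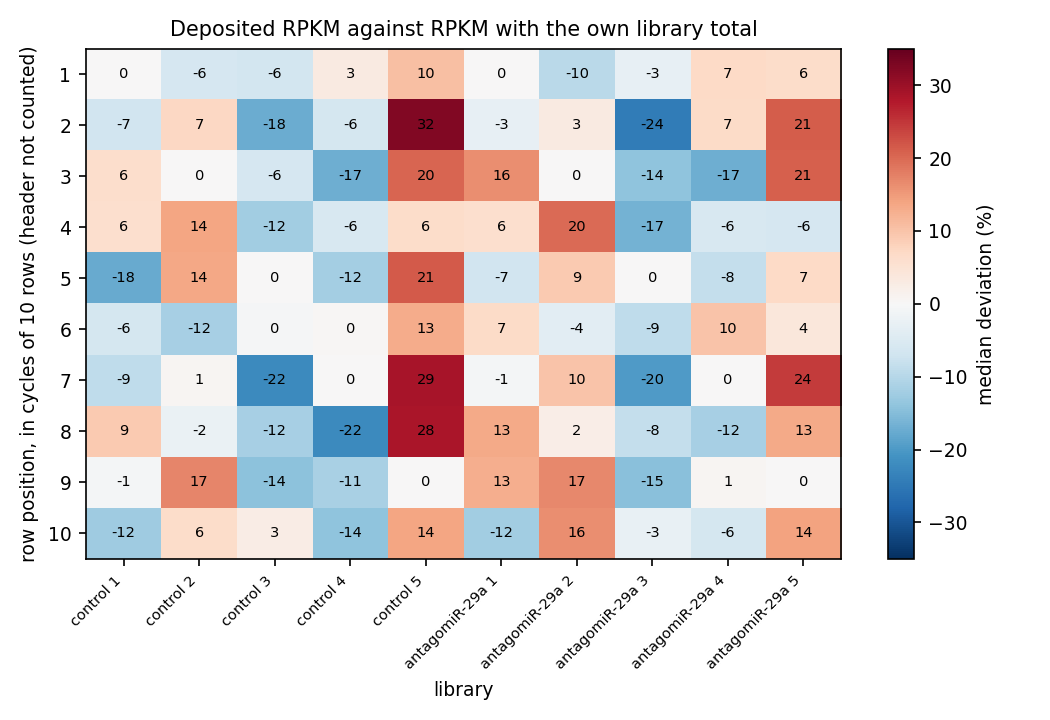
Median deviation, in percent, of the deposited RPKM from the RPKM computed with each library's own total, for each library (x axis) and each row position in cycles of 10 rows (y axis). Deviations run from -24.5% to 32.4%, and the deviation of a gene depends on its row.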

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

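The fits on RPKM and CPM recomputed with own library totals were chosen after seeing the data. All 9 called genes kept their direction in all 26 alternatives, which says little, since they were picked by p in the same libraries. The number of calls stayed within 1.5 times the reported 9 with limma-voom, without robust estimation, with RLE or upper quartile scaling, with no or a stricter count filter, with 1 surrogate variable and in the 4 fits on own totals. DESeq2 called 73 genes, 57 higher and 16 lower, all 9 among them. Of these, 72 were tested by edgeR, and all 72 had an edgeR unadjusted p under 0.05 and the same direction. Both tests used the same counts, so this adds no separate support. The simulated data, drawn with dispersions estimated by edgeR, gave DESeq2 more false calls than edgeR. An adjusted p limit of 0.1 gave 18 calls. The deposited RPKM gave 0 calls by limma-trend with either pseudocount, with 436 and 442 genes at an unadjusted p under 0.05; the divisors of the table raise the spread between libraries. Leaving out 1 library gave 0 to 8 edgeR calls, with at most 6 of the 9 shared, and the fit then has fewer samples. With the title number as a replicate block, edgeR called 0 genes, with 707 at an unadjusted p under 0.05. This fit leaves fewer residual degrees of freedom, and samples whose number occurs in 1 group add nothing to the group difference. The 0 calls may therefore in part reflect lost power. Only 4 numbers occur in both groups, their samples' deviations correlated at 0.01, -0.31, -0.09 and -0.09, and no antagomiR-29a sample correlated best with its own number, so the number was not taken as a pairing. Over the alternatives the adjusted p ranged from 7.33e-16 to 0.743 for Nfu_g_1_010009 (log2 fold change 0.83 to 0.97), from 7.46e-12 to 1 for Nfu_g_1_008034 (0.41 to 0.46) and from 2.67e-08 to 0.931 for Nfu_g_1_010469 (-0.97 to -0.75). The lowest values came from DESeq2. The highest came from the title number block for Nfu_g_1_010009 and Nfu_g_1_010469, and from the deposited RPKM for Nfu_g_1_008034. Nfu_g_1_018930 passed in 3 of 26. The other settings chosen beforehand for gene lists, miR-29 targets and miR-29 sites were not run, for lack of gene names. At this depth and spread, changes under 1.5-fold are mostly not detectable.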

Other observations

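The test of how the deposited RPKM were divided and the count of splits by genes at an unadjusted p under 0.001 were chosen after their results were seen; the removal of length and expression trends and the count of splits at 0.05 were added after the lean was seen and before their own values were computed. Some transcripts varied far more between libraries of the same group than others of like abundance. The 500 genes with the highest spread for their expression had a median SD within groups of 0.86 on the log2 scale, against 0.17 for all tested genes, and the highest was 4.47. Many varied together. The largest cluster held 159 genes with a median of 21.9 CPM, whose mean log2 deviation per library ran from -1.27 in control replicate 3 to 0.98 in antagomiR-29a replicate 2. Genes were picked and clustered by their deviations within groups, so the difference between groups did not enter the choice. For this cluster it was 0.07 log2 units, antagomiR-29a minus control (SD 0.77 in the control and 0.91 in the antagomiR-29a group, n = 5 each). It lay within the spread between replicates (two-sided exact permutation p = 0.897, not adjusted). With such spread a small difference would not be seen.

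A second cluster of 26 genes, at a median of 6.76 CPM, took widely separated levels. Its mean log2 deviations were -2.49, -2.08, -2.33, 1.87 and 1.82 in control replicates 1 to 5, and 1.26, 1, -2.50, 2.16 and 1.29 in antagomiR-29a replicates 1 to 5. Another cluster of 25 genes, at a median of 5.67 CPM, stood at -1.85 in control replicate 1, -2.38 in control replicate 3 and -2.63 in antagomiR-29a replicate 4, and between 0.84 and 1.26 in the other libraries. Control replicates 1 and 3 were low in both of these clusters, control replicate 2 and antagomiR-29a replicate 3 in the 26-gene cluster alone, and antagomiR-29a replicate 4 in the 25-gene cluster alone. Antagomir minus control, the 26-gene cluster differed by 1.28 log2 units (control SD 2.27, antagomiR-29a SD 1.81, two-sided exact permutation p = 0.476, not adjusted). The 25-gene cluster differed by 0.38 (control SD 1.77, antagomiR-29a SD 1.58). Both differences lay within the spread between replicates.

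High-spread genes may in part be neighbours. The deposited table held 35 pairs of neighbouring tested rows that were both among the 500, where 10000 random placements gave 13.2 on average and 29 at most (permutation p = 1e-04, the smallest they can give), and the median correlation of these pairs across the 10 libraries was 0.95, against 0.11 for random pairs of high-spread genes. Neighbouring rows could be copies of a gene, parts of a split gene model or genes of a shared haplotype, which were not told apart. Members of the 3 clusters were mostly not close together in the table. Another member lay within 10 rows for 19.5% of the cluster of 159 genes (exact 95% interval 13.6% to 26.5%). The share was 0% in that of 26 (up to 13.2%) and 8% in that of 25 (1% to 26%). Random sets of these sizes had medians of 11.3%, 0% and 0%. The shares were below the 50% set beforehand for a single compact stretch of the genome. A longer stretch could leave members further apart, and whether the rows follow the genome was not tested, so a single stretch is not excluded. The labels name no batch, dissection or genotype, and no biological explanation was tested.

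The called genes and the lean towards higher values in the antagomiR-29a group were set against other divisions of the same libraries. Of 100 splits into 5 and 5, drawn from 126 and the real one included, 2 called at least 9 genes. The other of these called 25 genes, and 86 splits called 0. A difference of at least 32 between genes higher and lower at an unadjusted p under 0.001 was reached by 4 of 100 splits (highest other 171). Both shares are under 5%, but they are not adjusted for the further measures taken on the same splits, so chance is not excluded for either. Chance also cannot be excluded for the numbers of genes at these unadjusted limits. At least 54 genes under 0.001 were found in 6 of 100 splits (highest other 195), and at least 1122 under 0.05 in 23 of 100 (highest other 2208). With every library thinned to 18489730 counts, 9 of 9 called genes kept an unadjusted p under 0.001 and their direction, and 6 genes were called. Since the 9 genes had been picked by lower p in the same counts, this was nearly fixed and does not decide on depth. Library totals did not differ between the groups beyond their spread (exact permutation p = 0.873). Log2 fold changes fell slightly with gene length across genes, which are not independent replicates (Spearman's rho -0.134), but with the trends on length and expression removed (rho -0.016) the difference at an unadjusted p under 0.001 was 35, against 31 in the same genes before, 3 of 100 splits refitted alike reached it (highest other 174), and all 9 calls were kept among 12; a response to antagomiR-29a remains a hypothesis, and other unrecorded differences between the samples stay open.

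The pattern of the deposited RPKM may come from a division in which the 10 library totals were used in turn down the rows of the table rather than across its columns. This accounts for 100% of the nonzero entries after rounding, all but 4 of 215535. The errors partly cancel in group means, where they shift the log2 fold change by between -0.0356 and 0.0723 depending on the row.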
